A study of Oncorhynchus mykiss with 7 samples.

How the data were processed

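RTgill-W1 is an established epithelial cell line from the gill of the rainbow trout, Oncorhynchus mykiss. Per the labels' protocols, cells were grown at 20 °C, seeded at 500000 cells per mL into 24-well plates and left for 24 h to attach. Wells then received L-15/ex, a simplified exposure medium, either alone (control) or with bacterial lipopolysaccharide (LPS, a cell wall component of Gram-negative bacteria) at 100 mg/L, and were kept for 4 h. RNA was extracted from each well, samples with an RNA integrity number above 8 were kept, and stranded mRNA libraries were read as pairs of 75 bp. The labels' protocols describe 4 replicate wells per treatment. The 7 libraries used here are 4 control and 3 LPS wells, so not every LPS well has a library here. Nothing in the labels says that wells came from separate cultures or passages, so the p-values measure the spread between wells, which may be technical.

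Per the submitters' processing notes, the authors used Trimmomatic 0.38, kallisto and edgeR. The reference transcriptome and the settings are not given in the sources used here. For each library the authors deposited estimated counts, which need not be whole, for 119270 RefSeq transcripts, and deposited TPM values, scaled by transcript length to a sum of 1000000, which were read but entered no test. A table of the whole series held the same estimated counts to within 5.0e-08. The authors also deposited a comparison of 22510 transcripts with log2 fold changes, average log2 CPM, p-values, adjusted p-values and an F statistic. That F statistic, a test score per the file headers, was not used. Its values are used only beside those computed here. Whether the strand was used in counting is not given in the sources used here, so reads of genes that overlap on opposite strands may be mixed.

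All 119270 transcript identifiers matched the RefSeq gene table of the assembly USDA_OmykA_1.1, which was used only for names. The files name no genome build, so no coordinates are given. Estimated counts were summed to 57432 genes and rounded to whole numbers. Only 10070 of these genes (17.5%), which held 30.1% of all counts, carried a symbol other than a locus number. The gene lists reach only genes with a symbol. The rainbow trout genome holds many near-identical gene copies, and kallisto divides reads that fit several transcripts among them. A gene whose summed estimate was within 0.1 of a whole number in every library was taken to share no reads with another gene, which held for 7606 of the genes tested. Values of other genes rest in part on that division.

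The libraries held between 11151516 and 14377910 estimated counts. At these depths, 3 counts, the most that a count of 0 allows, equal 0.209 to 0.269 CPM (counts scaled to a library of 1000000). That limit covers counting error only, since reads carry no molecular identifiers.

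The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 7 libraries, with TMM scaling, robust dispersion estimates and no covariate. Genes were kept by the default edgeR filter (a minimum count of 10 and a minimum total of 15), which left 27705. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values of LPS minus control. Standard errors (SE) and 95% intervals are Wald values from that fit. CPM values use the TMM-scaled library sizes and are given as mean ± SD, with n = 4 for control and n = 3 for LPS. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over 18 lists. The camera test was repeated with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes.

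The design, the alternatives, the 18 lists and the rule for named genes were set before the data were examined. The rule took the 6 largest increases and the 6 largest decreases among called genes that had a mean log2 CPM above 1, no overlap between the groups and a symbol that is not an uncharacterized locus. It added the 2 members of each list with the smallest p (6 for the tight junction and the cytokine lists), and il1b, il-8, tnf, il6, the more abundant claudins, occludin and tjp1. It gave 56 genes, of which some are not reported here. Other genes named to identify the called members of a list were chosen after their values were seen. The lists matched whole symbols and so missed forms such as il-8, cox-2 and oclna, and took in receptors such as ifngr1. Results are given for the lists as set, and, where the number of called members differs, also for revised lists made after the members' values had been seen. A further 5 lists were written and refined after seeing the data and appear only among the additional observations.

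The test was checked on simulated data for LPS against control, with counts drawn from the means of the real libraries and 200 genes changed. Of 27338 genes tested, it recovered 65.7% of genes changed by 1.5-fold, 80.6% of those changed by 2-fold and 92.4% of those changed by 4-fold. Of 187 genes called there, 28 (15%) were false, above the nominal 5% that the adjustment aims at. The check had first been set to fail above 10% false calls; after that failure its criterion was changed to the p-values of unchanged genes, of which 4.89% lay under 0.05 and 0.6% under 0.005. The 95% intervals held the true value for 95.2% of genes. With 3014 genes changed, 1664 were called, 4.4% of them falsely, and 52.8% of the changed genes were recovered. In the simulated list test a seeded list of 15 genes, all raised 1.5-fold, passed and 0 of 17 unchanged lists did. The simulated genes varied independently of each other, so this does not check the preset correlation for lists whose genes vary together.

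Alternatives were RLE and upper-quartile scaling, no filter, a filter of 10 counts in 3 samples, limma-voom, DESeq2 1.42.0, the replicate number as a block, unrounded counts, the transcripts as deposited, a fold threshold of 2, and leaving out each of the 7 libraries. At the transcript level a named gene is represented by its most abundant transcript. A fit of only the genes with whole counts was added after seeing the data. For each test, all 35 splits of the 7 libraries into groups of 3 and 4 were also fitted.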

Results

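Gene expression was measured by mRNA sequencing in RTgill-W1 rainbow trout gill cells kept for 4 h in medium alone (4 wells) or with 100 mg/L LPS (3 wells). The series title names inflammation and tight junctions of fish gill epithelia, so the comparison addresses which inflammatory and junction genes differed after LPS. The control libraries held 12501791, 12058966, 12889054 and 12802785 estimated counts and the LPS libraries 11151516, 13260521 and 14377910. Across genes, Spearman correlations between libraries were 0.986 to 0.991 within groups and 0.978 to 0.984 between groups. The first principal component held 35% of the variance and separated control from LPS libraries. Library pairs within a group differed by more than counting noise (chi-square per degree of freedom of 1.44 to 4.46), so no pair was counted as 1 library deposited more than once; this does not show that the wells were separate cultures. The coefficient of variation that edgeR terms biological, the spread beyond counting noise, was 6.2%.

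The matricellular protein gene ccn1 rose from 18.1 ± 1.05 CPM in control to 158 ± 2.47 CPM in LPS wells (log2 fold change 3.12, SE 0.06, edgeR adjusted p = 7.08e-21). Among called genes with a symbol, a mean log2 CPM above 1 and groups that did not overlap, the next largest increases were in tf (2.47), the nuclear receptor gene nr4a3 (2.40), the prostaglandin synthesis gene cox-2 (2.21), the early response gene ier3 (2.15) and the neutrophil chemokine gene il-8 (1.92). Under the same limits, the largest decreases were in her9, which encodes a hairy-related transcriptional repressor (-1.57), zbtb24 (-1.54), the stress-inducible gene sesn1 (-1.54), ier5l (-1.42), smo, a transducer of Hedgehog signals (-1.34), and the cyclin-dependent kinase inhibitor gene cdkn1cb (-1.33). By that choice, every LPS library lay on the same side of every control library for all 12 genes. The summed estimates of ccn1, nr4a3, cox-2, il-8, sesn1 and smo were not whole, so part of their reads was shared with other genes. For nr4a3, zbtb24 and cdkn1cb, the most abundant transcript alone did not pass the edgeR test (adjusted p = 0.098, 0.882 and 0.152).

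**Figure D1:**
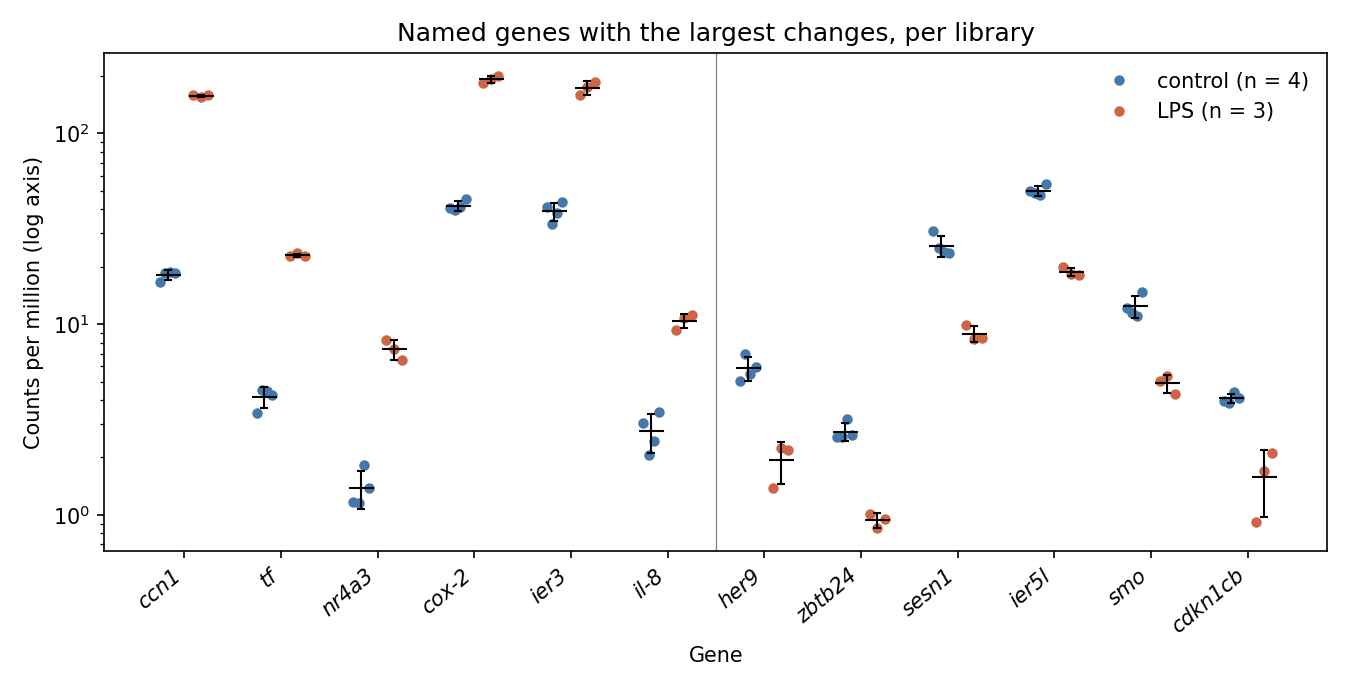
CPM on a log axis in each library for the 6 largest increases (left) and the 6 largest decreases (right) among called genes with a symbol, a mean log2 CPM above 1 and groups that do not overlap. Points are libraries (blue control, n = 4, and orange LPS, n = 3), horizontal bars are means and vertical bars SD. By that choice the groups do not overlap for any of the 12 genes. The mean of ccn1 moved from 18.1 to 158.

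In all, 3014 of 27705 genes tested (10.9%) were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1787 higher and 1227 lower after LPS. Most changes were small: 244 of the higher and 152 of the lower genes differed by more than 2-fold. Among genes with a symbol, 700 of 7086 were called (404 higher, 296 lower), and among long noncoding RNA genes 78 of 1348 (56 higher, 22 lower). The groups did not overlap for 21.2% of the genes tested, where chance gives 5.7%. The share of called genes that were higher was 59.3% with TMM scaling and 47% of 3152 with upper-quartile scaling, so the balance of increases and decreases depended on the scaling. The count was 1921 without LPS replicate 2, 1809 with DESeq2 and 760 when transcripts were tested as deposited.

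Immediate early genes and feedback regulators, which respond to stimuli within minutes to hours, moved most as a group. Of 29 measured members 20 rose, 6 fell and 3 did not pass the test; the counts adjusted over the list alone were the same. The transcription factor gene egr1 rose from 70.2 ± 4.65 to 263 ± 5.86 CPM (log2 fold change 1.91, SE 0.05, edgeR adjusted p = 2.25e-18), and fosl2, a component of the AP-1 transcription factor, rose from 17.1 ± 0.56 to 55.1 ± 2.80 CPM (1.68, SE 0.06, edgeR adjusted p = 2.74e-15). The MAP kinase phosphatase gene dusp1 (1.58) and the transcription factor gene cebpb (1.20) rose as well. The 6 members that fell were ier5l (-1.42), klf2a (-0.62), dusp6 (-0.61), zfp36l1b (-0.44), klf6a (-0.26) and mych (-0.26). The list stood above other genes by camera (adjusted p = 6.38e-09, median log2 fold change 0.76). With an estimated correlation the adjusted p was 0.31. In the revised list, made after seeing the data, 22 of 33 rose and 6 fell (camera adjusted p = 3.13e-10, or 0.2 with an estimated correlation).

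Cytokine and chemokine genes were the group tied most directly to inflammation. Of 15 measured members 4 rose, 0 fell and 11 did not pass the test, as also when adjusted over the list alone. Those 15 include the receptor genes ifngr1, ifngr1l, ifngr2a, ifngr2b, il17r, il17rc and il17rel, which the revised list leaves out. The interleukin gene il11 rose from 12.6 ± 0.82 to 26.3 ± 2.39 CPM (log2 fold change 1.07, SE 0.09, edgeR adjusted p = 1.97e-09) and il34 from 13.4 ± 1.06 to 19.8 ± 1.13 CPM (0.56, SE 0.09, edgeR adjusted p = 6.89e-05). The tumour necrosis factor gene tnfa rose from 0.23 ± 0.11 to 1.61 ± 0.45 CPM (2.75, SE 0.48, edgeR adjusted p = 4.61e-05), on 12 reads over the control libraries and 62 over the LPS libraries. The fourth was ifngr1 (0.63, SE 0.10), which encodes a receptor for interferon gamma and not a cytokine. For tnfa, il34 and ifngr1 the most abundant transcript alone did not pass (edgeR adjusted p = 0.124, 0.275 and 0.777). Of the other members with the smallest p, ifngr2b had a log2 fold change of 0.22 (SE 0.09, edgeR adjusted p = 0.124) and il17r of 0.40 (SE 0.20, edgeR adjusted p = 0.229). The chemokine gene il-8, which the list missed by its spelling, rose from 2.75 ± 0.63 to 10.4 ± 0.94 CPM (1.92, SE 0.16, edgeR adjusted p = 4.08e-09). The list stood above other genes by camera (adjusted p = 0.0292, median 0.26). With an estimated correlation the adjusted p was 0.41. The camera call was lost without control replicate 2 (adjusted p = 0.0635), LPS replicate 1 (0.0694) or LPS replicate 3 (0.0771). It was also lost with the replicate number as a block (camera adjusted p = 0.0755). In the revised list, made after seeing the data, 6 of 14 members rose (il11, il-8, tnfa, il34, tgfb1a and csf3a). Camera gave it an adjusted p of 0.0101, or 0.328 with an estimated correlation. Adjusted over that list alone, 6 were higher and 1, il10b (-0.89), was lower. The genes il1b (10.6 reads over all 7 libraries), il6 (1 read) and tnf (13 reads) fell below the count filter and were not tested.

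Of 6 measured members of the tight junction list as set, 0 rose and 0 fell by edgeR, also when adjusted over the list alone; 2 had an unadjusted p under 0.05, and neither DESeq2 nor limma-voom called any. Claudins are the membrane proteins that seal these junctions: cldn1 was at 8.08 ± 0.82 CPM in control and 7.83 ± 0.96 CPM in LPS wells (log2 fold change -0.04, 95% interval -0.31 to 0.23, edgeR adjusted p = 0.89), and cldn19 at 0.95 ± 0.26 and 0.80 ± 0.26 CPM (-0.26, interval -1.01 to 0.50). The scaffold gene tjp1b had a log2 fold change of 0.09 (interval -0.18 to 0.36), tjp3 of 0.36 (0.05 to 0.68), the polarity gene pard6a of 0.45 (0.11 to 0.78) and the adhesion receptor gene cxadr of 0.04 (-0.13 to 0.21), with edgeR adjusted p of 0.729, 0.146, 0.0802 and 0.826. The list did not stand apart from other genes by camera (adjusted p = 0.422, median 0.07), nor with an estimated correlation (0.576). In the revised list, made after seeing the data, 1 of 13 members rose, the junction adhesion gene igsf5b (0.81, edgeR adjusted p = 0.0411), 0 passed when adjusted over the list alone, and the camera adjusted p was 0.395.

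Coverage limited that comparison. Of 13 claudin genes with a symbol, 11 were too low to test, and 4 of them had under 1 read over all libraries. The occludin genes oclna and oclnb had 2 reads each over all 7 libraries and were not tested. Junction genes that carry only a locus number were not analysed here as members of the list. The adherens junction and desmosome list had 2 measured members, the cadherin gene cdh2 (0.07, SE 0.05) and the catenin gene ctnna2 (0.01, SE 0.24); neither was called by edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05, and the camera adjusted p was 0.706.

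**Figure D2:**
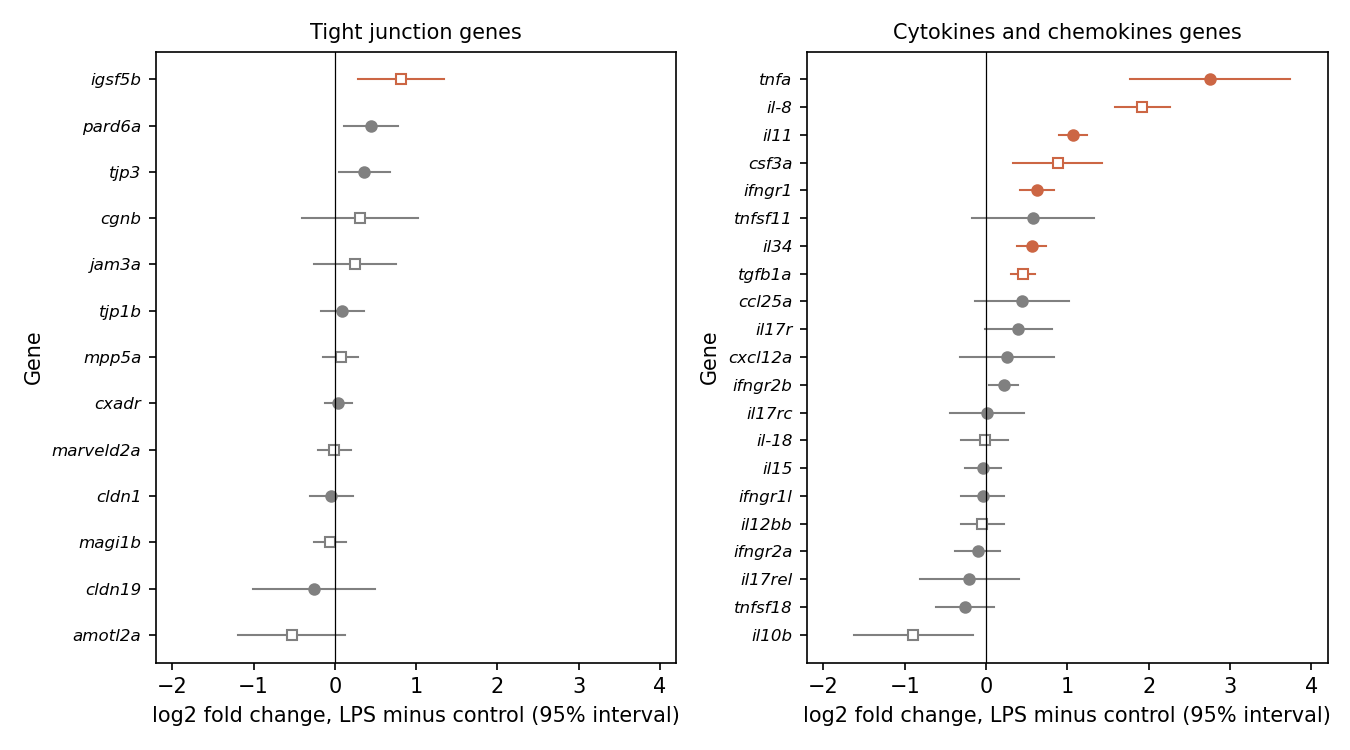
Log2 fold change of LPS minus control (x axis) with its 95% interval for each tested gene of the tight junction (left) and cytokine and chemokine (right) groups. Filled circles are members of the lists as set and open squares were added by the revised lists; orange marks an edgeR adjusted p under 0.05, reached by igsf5b alone on the left and by 7 genes on the right, with tnfa highest at 2.75.

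Among chaperone and unfolded protein response genes, 5 of 28 measured members rose and 0 fell. The heat shock genes hsp70a (264 ± 12.7 to 551 ± 50.1 CPM, log2 fold change 1.06, SE 0.06, edgeR adjusted p = 7.18e-08) and hsp70b (1.71, SE 0.13, edgeR adjusted p = 2.47e-04) rose with dnajb1b (1.09), bag3 (0.57) and hspb7 (0.27). The list median was 0.00 and camera gave an adjusted p of 0.344, while fry, which does not compare a list with other genes, gave 0.0432. Matrix remodelling genes had 5 of 28 members higher and 1 lower (camera adjusted p = 0.177, fry adjusted p = 0.00879). Among them has2, a hyaluronan synthase gene, rose from 8.32 ± 0.94 to 22.95 ± 3.08 CPM (1.47, SE 0.11, edgeR adjusted p = 4.68e-10). In the pattern recognition and NF-kB list 3 of 18 rose and 0 fell (camera adjusted p = 0.344), among them the kinase gene irak1 (0.50, edgeR adjusted p = 0.00218) and birc2 (0.24, edgeR adjusted p = 0.00481). The most abundant irak1 transcript had a log2 fold change of -0.05 (edgeR adjusted p = 0.995). That of birc2 did not pass (edgeR adjusted p = 0.146), though its log2 fold change in the authors' deposited table was 0.27. In the revised list 4 of 22 rose, with nfkbiab added (0.37), and the camera adjusted p was 0.456. Adjusted over the list alone, 4 members of the pattern recognition list as set (5 higher and 1 lower of the revised list) and, for matrix remodelling, 5 higher and 2 lower passed, with no such difference for chaperones.

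In the interferon response list 1 of 32 members rose, irf1b, an interferon regulatory factor (1.47, SE 0.14, edgeR adjusted p = 1.44e-07), and 1 fell, irf2bp2b, which encodes a partner protein of such a factor (-0.67, SE 0.09). Camera gave that list an adjusted p of 0.549. In the revised list, which leaves out irf2bp2b, 1 of 34 rose and 0 fell (0.99). No member of the acute phase and antimicrobial list passed edgeR or DESeq2 (0 of 12, with 2 at an unadjusted p under 0.05 and 1, saa, by limma-voom at an adjusted p of 0.0497); nccrp1 had -0.18 (SE 0.07), which edgeR called with upper-quartile scaling (adjusted p = 0.0357) and without LPS replicate 1 (0.0386), and arg2 0.11 (SE 0.05), and the camera adjusted p was 0.344. The list missed cox-2 by its spelling; in the revised list 1 of 9 rose, cox-2 (2.21, edgeR adjusted p = 8.31e-19), with a camera adjusted p of 0.128, or 0.328 with an estimated correlation. The revised lists left the counts of called members the same for 12 of the 18 lists. In the xenobiotic list 1 of 23 rose, the anion transporter gene slco3a1 (0.49, SE 0.06), and the aryl hydrocarbon receptor gene ahr1a had -0.60 (SE 0.34, edgeR adjusted p = 0.301). The camera adjusted p was 0.713. Of the oxidative stress genes 1 of 18 rose, srxn1 (0.32, SE 0.06), and 3 fell, with a camera adjusted p of 0.344 for the list. The most abundant srxn1 transcript alone did not pass (edgeR adjusted p = 0.133), though its log2 fold change in the authors' deposited table was 0.30. Adjusted over the list alone, 3 oxidative stress genes were higher and 5 lower.

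Cell death genes moved both ways, with tnfrsf21 (0.38, SE 0.06) among 2 of 14 that rose and the pro-apoptotic gene bcl2l11 (-0.87, SE 0.13) the 1 that fell, though its most abundant transcript alone did not pass (edgeR adjusted p = 0.955). Their median was 0.00 and their mean -0.06, while camera gave an upward direction (adjusted p = 0.735). Of 23 cell cycle genes 0 rose and 2 fell, the replication helicase gene mcm7 (-0.25, SE 0.06) and e2f1 (-0.80, SE 0.25; camera adjusted p = 0.177). The mcm7 call was lost without LPS replicate 3 (edgeR adjusted p = 0.0502) and with DESeq2 (0.0538). The e2f1 call was lost in 10 of 16 alternatives, among them DESeq2, limma-voom and leaving out any 1 of 6 libraries, all but control replicate 2 (0.0668 to 0.121). Counts adjusted over the list alone were the same for the interferon, acute phase, xenobiotic, cell death and cell cycle lists as set. The revised acute phase list had 1 higher and 1 lower, nccrp1, when adjusted over the list alone.

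**Figure D3:**
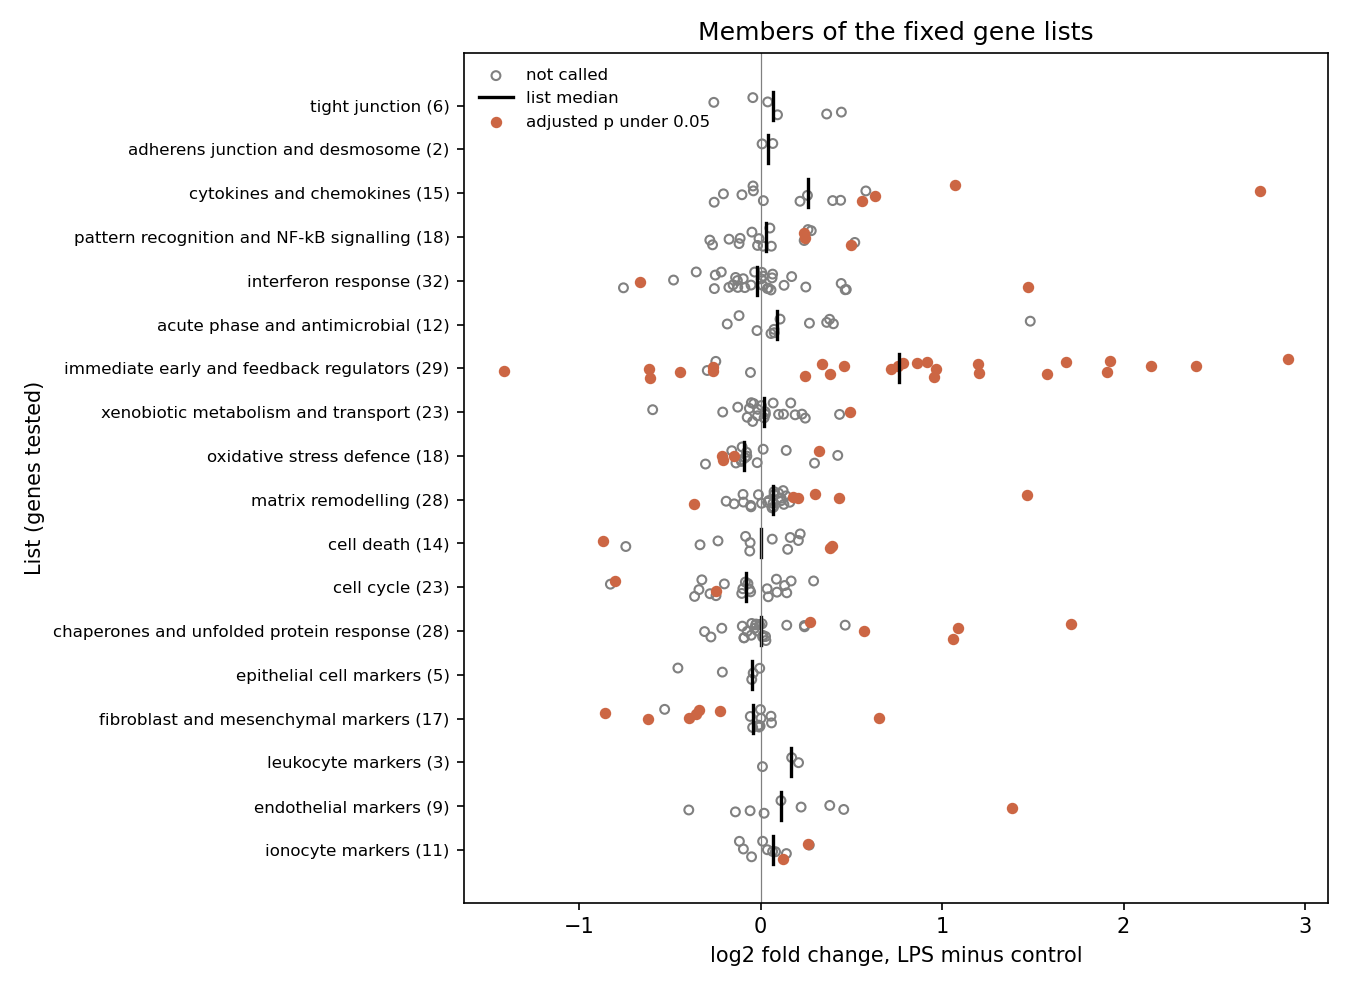
Log2 fold change of LPS minus control (x axis) for each measured member of the 18 lists as set (rows, with the number of genes tested). Filled orange points have an edgeR adjusted p under 0.05, open points do not, and black bars are list medians; the immediate early list has the highest median, 0.76, and the tight junction list has no filled point.

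Marker genes of cell types were compared as a check on the make-up of the cultures. The epithelial keratin gene krt79 was at 10400 ± 189 CPM in control and 10060 ± 344 CPM in LPS wells (log2 fold change -0.05, SE 0.03, edgeR adjusted p = 0.344). The keratin gene krt18b was at 104 and 101 CPM (-0.04, SE 0.05). None of 5 epithelial markers was called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.344). The check rests mainly on these keratins. In control wells grhl2b was at 0.96 CPM (-0.46, SE 0.36) and esrp1 at 0.80 CPM (-0.21, SE 0.37), too low to show small changes. The revised epithelial list leaves out krtcap2. In control wells the mesenchymal markers col1a1a, fap and pdgfra were at 1388, 159 and 126 CPM, while others, such as postna (0.91 CPM), were low. The check therefore compares the groups and does not establish how epithelial the cultures were. Of 17 fibroblast and mesenchymal markers 6 fell and 1 rose. The growth factor receptor gene pdgfra fell from 126 ± 4.74 to 69.4 ± 4.52 CPM (-0.85, SE 0.05, edgeR adjusted p = 2.09e-11) and the collagen gene col1a2 from 717 ± 28.4 to 546 ± 33.4 CPM (-0.39, SE 0.04, edgeR adjusted p = 5.31e-07), while vim had -0.01 (SE 0.05). Adjusted over the list alone, 7 fell and 1 rose. Camera gave the list an adjusted p of 0.0517, and 0.41 with an estimated correlation. The list passed in 5 of 18 alternatives, with limma-voom (0.00692), fry (0.00932), upper-quartile scaling (0.0432) and without control replicate 4 (0.0427) or LPS replicate 1 (0.0485), over a range of 0.00692 to 0.41.

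Of the 3 measured leukocyte markers, cd3e was at 4.06 ± 0.41 and 4.58 ± 0.74 CPM (0.17, SE 0.16) fcer1g at 0.91 ± 0.27 and 1.06 ± 0.12 CPM (0.21, SE 0.33) and cd40 at 19.96 ± 1.15 and 20.09 ± 1.22 CPM (0.01, SE 0.08) in control and LPS wells; 0 of 3 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.549). Of 9 endothelial markers 1 rose, sox17 (1.39, SE 0.39, edgeR adjusted p = 0.0175, lost in 3 of 15 alternatives, among them without LPS replicate 3 at 0.154 and for its most abundant transcript alone at 0.393), and egfl7 had 0.38 (SE 0.15). The camera adjusted p was 0.344. Of 11 ionocyte markers 2 rose, the proton pump subunit gene atp6v1f (0.26, SE 0.07, edgeR adjusted p = 0.0153) and the ion cotransporter gene slc12a2 (0.13, SE 0.04, edgeR adjusted p = 0.0496), with a camera adjusted p of 0.462. The slc12a2 call was lost in 14 of 16 alternatives, among them RLE and upper-quartile scaling, both other filters, limma-voom, DESeq2 and leaving out any 1 of 6 libraries, all but control replicate 2 (edgeR adjusted p = 0.0701 to 0.2). The atp6v1f call was lost in 6 of 16 alternatives, for its most abundant transcript alone (0.318), with DESeq2 (0.0859) and without any 1 of 4 libraries, control replicates 2 and 3 and LPS replicates 2 and 3 (0.0527 to 0.0993). Counts adjusted over the list alone were the same for these 3 lists and for the epithelial list.

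The authors' deposited table compares the same groups by transcript. At an adjusted p under 0.05 the authors' deposited table holds 883 of 22510 transcripts, 610 higher and 273 lower after LPS, and its up and down tags mark 173 and 49 that differ by more than 2-fold. In the authors' deposited table ccn1 has a log2 fold change of 3.10, egr1 of 1.89, il-8 of 1.90, cldn1 of -0.06 and pdgfra of -0.87. Testing all 43870 transcripts that passed the filter here called 760, and 679 transcripts were called in both, all with the same sign. Across the 22510 shared transcripts, which are not independent replicates, Pearson and Spearman correlations of the log2 fold changes were both 1.0 after rounding. The transcripts called in the authors' deposited table belong to 851 genes, of which 799 were called by edgeR on counts summed per gene.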

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

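The test for a control library far from the other 3 was set before the data were examined; the weighing of the collagen and transcript patterns was chosen only after the result was seen, and the splits of the libraries were set beforehand. Among 58 measures (the 56 named genes, total counts and the share of counts in the most abundant transcripts), 4 had a control library whose gap to the nearest other control was large for the range of the group, where chance gives about 2.9. For ccn1, control replicate 1 lay at 16.6 CPM against 18.6, 18.8 and 18.6 (gap over range 0.889). For zbtb24, control replicate 3 lay at 3.19 CPM against 2.57, 2.55 and 2.62 (0.887). For il11, control replicate 1 lay at 13.8 CPM against 12.16, 11.99 and 12.25 (0.853), and for has2, control replicate 4 lay at 9.71 CPM against 7.94, 7.64 and 7.97 (0.843). In each case the control libraries stayed on their side of all 3 LPS libraries, which the naming rule required for ccn1 and zbtb24.

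For the count of called genes, only the real split, 1 of 35, gave as many, with 3014 genes against at most 241 in the others. Each other split mixes LPS and control wells within a group, so a difference between them widens the spread there and can lower its count. The splits alone therefore do not exclude chance for this count. With the preset correlation, only the real split gave 2 called lists, against at most 1 in the others. It also gave the smallest camera p of the cytokine and chemokine list, 0.00324 against 0.00684 as the smallest of the others. These margins are narrow, and 1 of 35 is the lowest share that the splits can give. Chance is therefore not excluded for the number of called lists or for the cytokine list. With an estimated correlation 0 lists were called and the cytokine list had a camera adjusted p of 0.41. Its call was also lost with the replicate number as a block (0.0755). The same went for leaving out control replicate 2 (0.0635), LPS replicate 1 (0.0694) or LPS replicate 3 (0.0771). Nor can chance be excluded for the tight junction list, where 14 of 35 splits gave a camera p as small as the real one of 0.282. The smallest was 0.0333.

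Of 4 type I collagen genes 3 fell after LPS, as did pdgfra; col1a1 had -0.53 (edgeR adjusted p = 0.0604). Fewer mesenchymal cells in the LPS wells would lower the other mesenchymal markers about as much as col1a1a (-0.34, 95% interval -0.44 to -0.24), if the same cells make them. Whether they do was not tested. Of the 12 other markers, 9 had a 95% interval wholly above -0.34. Among these 9, vim and fap lay near 0 and tcf21 rose. Also among them, prrx1b fell by less (-0.22), with an interval (-0.33 to -0.11) that overlaps that of col1a1a. The interval of sparc (-0.04, interval -0.28 to 0.19) overlaps that of col1a1a too. Outside the 9, twist2 fell by more (-0.62). Reads moved between the type I collagen genes would leave their sum alone, but the summed CPM of the 4 genes was 2321 ± 132 in control and 1794 ± 105 in LPS wells (log2 fold change -0.37, SE 0.06), and pdgfra shared no reads. An effect of LPS on these genes stays open and may act on some mesenchymal genes and not on others, as may a difference between wells that the labels do not record.

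More than 32-fold differences in the authors' deposited table occur for 18 transcripts (log2 fold changes up to 9.99 in size), and 5 of them have an adjusted p under 0.05. Estimated reads moved between transcripts of the same gene are a candidate explanation, since the median absolute log2 fold change of the genes' summed counts was 0.13, and 0 of these 18 genes differed by more than 2-fold. Of the 18 transcripts, 10 vary within a group, from under 1 estimated read in 1 library to 20 or more in another. LPS alone changing which transcript is made would not give such jumps. These 10 were picked by the jumps, however, and the jumps are estimates from shared reads too. The groups did not overlap for 10 of the 18 transcripts, which need not be the same ones. LPS and the division of reads cannot be told apart for these transcripts, because every value is an estimate from shared reads.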

How the results depend on the processing

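The fit of genes with whole counts and the revised lists were chosen only after the result was seen; all other alternatives were set before. The 3014 called genes became 760 with transcripts as deposited, 1809 with DESeq2 (1079 adjusted p not given) and 396 with a fold threshold of 2. When only genes with whole counts were fitted, 994 of 7588 were called. The fit of all genes called 743 of 7606 such genes (740 called in both). The coefficient of variation that edgeR terms biological was 67.4% for transcripts against 6.2% for genes. It takes in any spread beyond counting noise, the division of reads among transcripts included. A wider spread makes calls harder. Whether it accounts for the whole drop with transcripts was not tested. For srxn1, birc2 and atp6v1f the transcript in the authors' deposited table changed about as much as the gene (0.30, 0.27 and 0.25 against 0.32, 0.24 and 0.26). Their lost calls thus do not show that the change rests on other transcripts. For others, such as irak1 (-0.06 against 0.50), the transcript and the gene differed. The cause was not tested for DESeq2 or for the rise from 743 to 994 either. Leaving out 1 library gave 1921 (without LPS replicate 2, 61.5% of the 3014 kept) to 3145. The other 7 alternatives, the replicate block among them, stayed within 1.5 times. Upper-quartile scaling moved the median of all genes by -0.03. Replicate numbers did not pair the libraries (correlations of deviations 0.04, -0.07 and -0.06; 1 of 3 best with its own number): the replicate block called 2926 genes, 84.4% of the 3014 kept, and 1 list, with the cytokine list at adjusted p = 0.0755. The 2 called lists became 0 with an estimated inter-gene correlation (cytokine list adjusted p = 0.41), 5 with fry, which does not compare a list with other genes, and 1 (without control replicate 2) to 3 without 1 library. Without 1 library the cytokine list ranged from adjusted p = 0.0212 to 0.0771, lost without control replicate 2 (0.0635), LPS replicate 1 (0.0694) or LPS replicate 3 (0.0771), and the tight junction list from 0.32 to 0.62. The tight junction list kept its direction and side of the threshold under all 18 alternatives. Of 56 named genes 16 kept their direction but changed side of the threshold in at least 1 alternative, 9 of them only with transcripts as deposited, and irak1 lost its call and reversed there (-0.05, adjusted p = 0.995; the cause was not tested). Transcripts called in both this fit and the authors' deposited table were 679, or 192 with more than 2-fold in both. Counts below the filter left il1b, il6, occludins and 11 of 13 claudins untested, and the cause of these low counts was not tested.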

Other observations

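The 5 lists below were written, and all tests on them chosen, only after the result was seen. Targets of serum response factor and YAP, transcription regulators that respond to the actin cytoskeleton, had 9 of 19 measured members higher and 0 lower. They include ccn1 (3.12), ccn2a (165 ± 8.23 to 585 ± 15.7 CPM, log2 fold change 1.83, SE 0.04), the actin nucleator gene lmod1b (1.38), the focal adhesion gene zyx (0.32) and the actin gene actb (0.22). Camera over the 5 lists gave an adjusted p of 1.79e-07, and 0.0107 with an estimated correlation. Without the 3 members over 2-fold apart, which prompted the list, 6 of 16 rose, with a camera adjusted p of 0.00169, and 0.0604 with an estimated correlation. The list was made with its members' values known, so no p here is an independent test, and whether these genes rose as a group stays open.

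Developmental transcription factor genes had 13 of 37 members lower and 5 higher after LPS, among them her9 (-1.57), hoxa2b (-1.33), dlx2a (-1.22) and nr2f2 (-1.06) lower and osr2 (1.30) and tcf21 (0.66) higher. Camera gave an adjusted p of 0.00476, and 0.038 with an estimated correlation. That these genes fell as a group is a hypothesis that the remaining members leave open: without the 8 members over 2-fold apart the camera adjusted p was 0.0695, and 0.174 with an estimated correlation. These members, too, were chosen with their values known.

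Circadian clock genes changed in both directions. The called members were cipcb (1.07), nfil3 (0.79) and nocta (0.75), which rose, and bhlhe40 (-0.82), per1b (-0.78) and dbpb (-0.73), which fell, out of 18. The called members thus did not move in 1 direction (camera adjusted p = 0.655). Both directions were known when the list was written, so this is a description and not a test. Of 37 ribosomal protein genes 0 rose and 5 fell by small amounts, such as rpl10 (-0.21) and rps3 (-0.24), with a camera adjusted p of 0.0556, and 0.734 with an estimated correlation. Of 15 cholesterol synthesis genes 2 rose, hmgcs1 (0.24) and srebf2 (0.14), and 2 fell, lss (-0.35) and insig1 (-0.29), with a camera adjusted p of 0.864.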
